A study of Mus musculus with 10 samples.

How the data were processed

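Left ear skin of MC903-treated mice was profiled in 10 samples, 5 gavaged with vehicle and 5 with the urotensin II receptor antagonist GSK1562590. Per the labels' protocols, RNA was extracted with Trnzol reagent and chloroform, mRNA was selected with oligo(dT) beads, fragmented and copied with random hexamers, and the libraries were sequenced as DNA nanoballs. The protocol mentions no step that marks the strand, so reads of overlapping genes on opposite strands may not have been told apart, which was not tested. HISAT is named per the submitters' processing notes, without a version, and the counting tool, annotation, filters and genome build are not given in the sources used here.

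One table of 19703 protein-coding genes was used. Per the file headers, the authors deposited for each library estimated counts (read counts that need not be whole, here called expected counts), TPM and FPKM, with group means of each. The authors also deposited a comparison of both groups with log2 fold changes, p-values and adjusted p-values (q-values) from DESeq2, per the file headers. The deposited FPKM values were only looked at for their range. Every per-library column was matched to its sample by the sample's title, and 0 per-library columns were left unmatched. One line of the table was empty, and the gene it would have held was not analysed here. To place the table's coordinates, its genes were matched by Ensembl identifier to the GENCODE annotation of mouse build GRCm38. Of 18930 matched genes, 18912 overlapped their reference gene on the same chromosome, so positions are given as the table has them and read as 1-based positions on GRCm38.

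Expected counts were rounded to whole numbers. Library totals ranged from 20183024 to 20606007. Genes were kept by edgeR's filterByExpr with the group (at least about 10 counts in enough samples and 15 in total), which left 15174, and scaled with TMM factors of 0.972 to 1.04. Groups were compared with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test, with group as the single term, Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05 on the adjusted p. A standard error is the fold change divided by the square root of its F statistic. The common biological coefficient of variation was 16.3%. CPM are TMM-scaled, and log2 CPM carry a prior count of 2. In counts simulated from these libraries for the comparison of 5 with 5, over 15174 genes, the same code tested on simulated data recovered 53.7% of 67 genes changed 1.5-fold, 83.6% of 67 changed 2-fold and 95.5% of 66 changed 4-fold, and called 13 of 14872 unchanged genes. The simulation drew each gene independently and changed few of them. These rates need not hold where genes vary together or many change.

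Before the data were examined, 31 gene lists with 691 entries were fixed, for itch, inflammation, epidermis, leukocyte types and the other tissues an ear can hold. Of these, 673 were found by symbol, 5 by an older symbol and 13 were absent from the table. There were 18 genes in more than one list. The 29 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list moves in one direction without comparing it with other genes. Each list's mean log2 CPM was compared between groups by an exact two-sided permutation test over 252 assignments, adjusted over the lists. Gene ontology and KEGG terms of 15 to 300 tested genes were taken from the table itself and tested with camera in the same way.

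Genes were named by a rule fixed before the data were examined. They were the 3 urotensin genes, the 12 largest called rises and 12 largest called falls among genes with a mean log2 CPM of at least 1 and an established symbol, the 4 members with the smallest p of each called list, 3 of each of 5 central lists and 1 of every other list. This gave 103 genes, of which 101 could be tested. The counts include 1 named gene and 1 list that are not reported here. Other genes are named with a statement that they were chosen after their values were seen, or as members of a list or of the closing section's tests.

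Libraries were compared for duplicates over genes with a mean of at least 100 counts. The squared difference of a pair was at least 21.5 times that of sampling noise in every pair, so no library was counted as a copy of another. The labels give no batch. Alternatives covered normalization, filters, DESeq2 1.42.0, limma-voom with sample weights, robust estimation, a 2-fold threshold, each library left out, list scores or 1 surrogate variable (sva 3.50.0) as covariates, and limma-trend on the deposited TPM with pseudocounts of 1 and 0.1. Covariates made from the cartilage and interferon lists were added after the data were seen.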

Results

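Gene expression was measured by RNA-seq in the left ear skin of mice whose ears had been painted with MC903. MC903, also called calcipotriol, is a vitamin D analogue that provokes skin inflammation and itch resembling atopic dermatitis. It was applied on 7 consecutive days and again on day 8, when the mice were gavaged either with vehicle or with GSK1562590, an antagonist of the urotensin II receptor, at 5 mg/kg in 100 µl. Per the labels, ear skin was taken on day 13. The vehicle group held 5 samples and the antagonist group 5 samples. Summed over protein-coding genes, the libraries held 20183024 to 20606007 expected counts, 20333134 ± 170117 in the vehicle group and 20373505 ± 162466 in the antagonist group (SD, n = 5 each), and 17351 to 17516 genes had at least 1 count. No ear without MC903 was analysed here, so the levels have no untreated baseline. The labels number the samples but do not say that each came from a separate mouse, so the p-values measure only the spread between these samples.

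The comparison of antagonist with vehicle asked how blocking the urotensin II receptor altered the expression of itch and inflammatory genes in inflamed ear skin. Antagonist ears had lower levels of leukocyte marker, chemokine, cytokine, collagen and cell division genes, and higher levels of some barrier and hair follicle genes. Of 29 gene lists, camera with a preset correlation called 16, 14 lower and 2 higher, while 0 were called with an estimated correlation, where 3 had an unadjusted p under 0.05 and the smallest adjusted p was 0.265. Among the clearest falls were Col3a1, a fibrillar collagen, from 4309 ± 1175 to 969 ± 442 CPM (counts scaled to library size; SD, n = 5), and Cxcl5, a neutrophil-attracting chemokine, from 92.7 ± 34.4 to 17.9 ± 6.07 CPM. Galnt15, an enzyme of O-glycosylation, rose from 133 ± 24.4 to 702 ± 297 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5176 of 15174 tested genes had an adjusted p under 0.05, of which 2530 were higher and 2646 lower in antagonist ears. The falls were larger: 597 called genes fell by a factor of 2 or more and 224 rose by as much, and at a factor of 4 or more the numbers were 79 and 32. The first principal component held 49.1% of the variance and put all vehicle libraries at negative and all antagonist libraries at positive scores.

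Markers of cartilage moved with the groups. The mean log2 CPM of the cartilage list was 4.89 ± 0.38 in vehicle and 3.18 ± 0.81 in antagonist libraries (SD, n = 5), and group membership accounted for 69.7% of its variance. When this score was added to the edgeR model as a covariate, a step chosen after the data were seen, 0 genes were called and 1841 had an unadjusted p under 0.05, so the calls of single genes below hold for the model without it. Of the 5176 genes called without it 5009 kept their sign, the median ratio of their log2 fold change with the covariate to that without was 0.69, and their SE grew by a median factor of 1.80. Camera with a preset correlation and this covariate still called the type 2, cytokine, chemokine, fibroblast and cell division lists. It also called the T and NK cell, neutrophil, macrophage, eosinophil and dendritic cell lists. The mast cell and basophil list and the red blood cell list lost their calls, and the cartilage list cannot be tested with its own score.

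The receptor that the antagonist binds was scarce in ear skin. Uts2r, also called GPR14, on chromosome 11 from 121160271 to 121161973, had 46 to 93 counts per vehicle library and 7 to 133 counts per antagonist library. This gave 3.21 ± 0.774 and 3.36 ± 2.73 CPM (SD, n = 5), a log2 fold change of 0.065 ± 0.54 (SE) with an adjusted p of 0.939 by edgeR. The sign of this difference turned in several alternative analyses, and the antagonist libraries ranged from 0.347 to 6.24 CPM. Both ligand genes, Uts2 on chromosome 4 and Uts2b on chromosome 16, had at most 1 expected count in every library and were not tested, so a difference in them was not detectable at this depth.

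The genes with the largest called falls included several known from fibroblasts, though whole ear skin does not show which cells made them. C1qtnf3, a secreted protein of the C1q and TNF family, was 14.7 times lower, at 15.3 ± 13.7 CPM in vehicle and 1.03 ± 0.486 CPM in antagonist ears, and its log2 fold change of −3.88 was −3.16 without vehicle replicate 12. Serpinb6d, a serine protease inhibitor, was 14.6 times lower (log2 fold change −3.87 ± 0.34 SE, adjusted p = 0.000332 by edgeR). Lrrc15, a surface protein of activated fibroblasts, had a log2 fold change of −3.27, or −2.65 without vehicle replicate 12. Crabp1, which binds retinoic acid, Sfrp2, a secreted Wnt modulator, and Mfap4, an elastic fibre protein, fell by factors of 5.83, 6.18 and 6.21. In all 5 antagonist libraries these 6 genes lay below all 5 vehicle libraries.

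The largest rise was that of Trim63, a ubiquitin ligase of muscle breakdown, from 2.61 ± 0.907 to 34.9 ± 34.7 CPM (SD, n = 5). Its log2 fold change of 3.74 was 2.99 without antagonist replicate 8, and its adjusted p by edgeR was 0.00409 with all libraries. Depp1, a FoxO-regulated gene, rose by 2.53 ± 0.55 (log2, SE), Wfikkn2, a secreted myostatin inhibitor, by 2.49 ± 0.35, and Fga, the fibrinogen alpha chain, by 2.45 ± 0.43. Depp1 was uneven among antagonist libraries, at 63.3 ± 42.5 CPM. Antagonist replicate 4, at 10.0 CPM, lay below vehicle replicate 12, at 16.0 CPM. In the lowest of 26 alternatives the log2 fold change of Depp1 was 0.047. Galnt15 was 5.29 times higher, with an adjusted p of 0.000808 by edgeR. Pdk4, which restrains pyruvate oxidation, had a log2 fold change of 2.27 and an adjusted p of 0.0172 by edgeR, and its antagonist values spread widely, at 145 ± 113 CPM. Pdk4 missed the threshold under limma-voom with sample weights (adjusted p = 0.0517) and limma-trend on TPM (0.0781 with a pseudocount of 1, 0.0815 with 0.1), and its sign turned with the cartilage covariate.

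**Figure D1:**
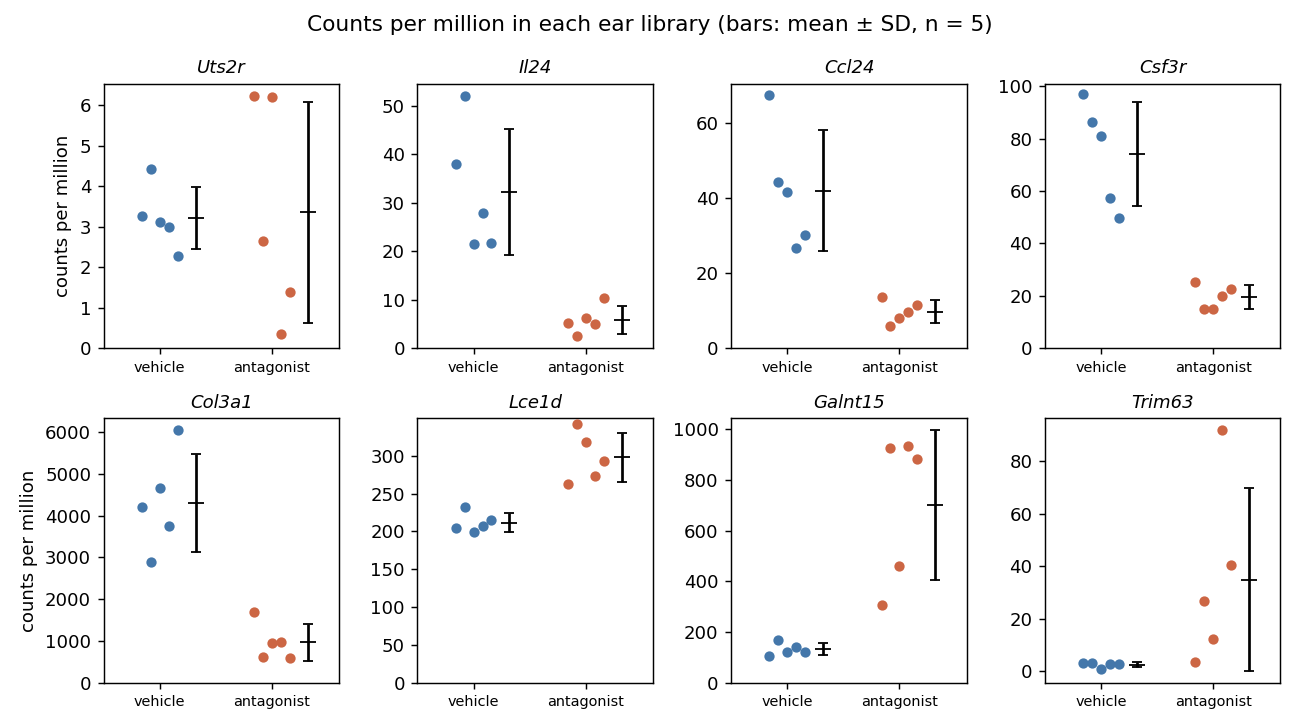
Expression in CPM (y axis) of 8 genes in each of the 10 ear libraries, by group (x axis); points are libraries, and bars give the mean and SD of 5. Il24, Ccl24, Csf3r and Col3a1 are lower in every antagonist library than in any vehicle library, Lce1d, Galnt15 and Trim63 are higher, and Uts2r overlaps.

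Type 2 and alarmin genes, the cytokine axis of atopic dermatitis, fell as a list. Of 25 tested members, 17 fell, 0 rose and 8 did not pass (17 fell and 1 rose when adjusted over the list alone). Ccl24, an eosinophil attractant, fell from 41.9 ± 16.0 to 9.70 ± 3.01 CPM (SD, n = 5). Il13ra2, the decoy receptor of interleukin 13, fell by 1.72 ± 0.26 (log2, SE), and Il2rg, the shared cytokine receptor chain, by 1.13 ± 0.14. Of the upstream cytokines the alarmin Il33 fell by 0.62 ± 0.18, while Tslp, with a log2 fold change of 0.83 ± 0.59 (adjusted p = 0.292 by edgeR), and Il4, with 0.18 ± 0.40, did not pass. Il5, Il9, Il13, Il25 and Il31 were removed by the filter on low counts and not tested. The list passed camera with a preset correlation (adjusted p = 7.2e-05), with an adjusted p = 0.265 with an estimated correlation.

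The inflammatory cytokine list and the chemokine list were lower too. The cytokine list holds pro- and anti-inflammatory cytokines and their immediate targets. Among its 23 tested genes 9 fell and 0 rose (12 fell when adjusted over the list alone). The falls were led by Socs3, a feedback inhibitor of cytokine signalling, with a log2 fold change of −1.11 ± 0.12 (SE). The interleukin 10 family members Il19 and Il24 stood at −2.29 ± 0.30 and −2.48 ± 0.35, and the interleukin 1 receptor antagonist Il1rn at −0.64 ± 0.10. The cytokine list had an adjusted p of 0.000131 by camera and an adjusted p = 0.265 with an estimated correlation. Among 32 chemokines 13 fell and 2 rose (15 fell and 2 rose when adjusted over the list alone). Beside Cxcl5 and Ccl24, Ccl21a, a chemokine that attracts dendritic cells and T cells, fell by 0.99 ± 0.12. The risers, named after their values were seen, were Ccl27a and Cxcl13, with log2 fold changes of 1.18 ± 0.27 and 1.34 ± 0.44. The chemokine list had an adjusted p of 5.96e-05 by camera and an adjusted p = 0.265 with an estimated correlation.

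Marker lists of every leukocyte type tested were lower in antagonist ears. T and NK cell markers fell in 16 of 23 tested genes and rose in 0 (22 fell when adjusted over the list alone), with Cd4 falling by 1.94 ± 0.32 and Icos, a T cell costimulator, by 1.71 ± 0.23 (log2, SE). Neutrophil markers fell in 12 of 15 and rose in 0 (12 over the list alone). Csf3r, the receptor of granulocyte colony-stimulating factor, fell from 74.3 ± 19.95 to 19.6 ± 4.48 CPM and Trem1 from 25.2 ± 4.80 to 5.97 ± 2.33 CPM (SD, n = 5). Macrophage markers fell in 12 of 22 and rose in 1, Mertk, named after its value was seen (the same numbers over the list alone), with the monocyte receptor Ccr2 at a log2 fold change of −2.07 ± 0.26. All 7 tested eosinophil markers fell, also when adjusted over the list alone. Dendritic and Langerhans cell markers fell in 11 of 17 and rose in 0 (11 over the list alone), with Cd209a falling by 2.08 ± 0.30. Mast cell and basophil markers fell in 8 of 15 and rose in 1, the tryptase Tpsb2, named after its value was seen (9 and 1 over the list alone), with the basophil protease Prss34 at −3.06 ± 0.64, and at −3.70 without antagonist replicate 4.

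These 6 leukocyte lists passed camera with a preset correlation, with adjusted p of 1.87e-08 for T and NK cells, 7.39e-05 for neutrophils, 7.17e-05 for macrophages, 0.000916 for eosinophils, 1.74e-05 for dendritic cells and 0.00492 for mast cells and basophils. In the same order the adjusted p with an estimated correlation was 0.291, 0.377, 0.377, 0.265, 0.265 and 0.592. The mean log2 CPM per library was also compared by an exact two-sided permutation test. The first 5 lists had an adjusted permutation p of 0.0192 from a p of 0.00794, the smallest that 252 assignments of 5 against 5 can give, and the mast cell and basophil list had an adjusted permutation p of 0.0432. The latter list missed the threshold under fry (adjusted p = 0.0599) and with the cartilage covariate (0.261). Only 4 B and plasma cell genes were tested, too few for a list test, and 3 of them fell (4 over the list alone), among them Cd22 with a log2 fold change of −1.08 ± 0.20.

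Of 28 tested fibroblast and extracellular matrix genes 21 fell and 1 rose (22 and 1 when adjusted over the list alone). Beside Col3a1, Col5a1, another collagen, fell from 260 ± 94.9 to 60.3 ± 20.01 CPM, the matrix protein Tnc from 888 ± 235 to 297 ± 80.6 CPM and the proteoglycan Lum from 772 ± 153 to 239 ± 88.4 CPM (SD, n = 5). The riser, named after its value was seen, was the collagen cross-linking enzyme Lox, with a log2 fold change of 0.46 ± 0.11. The list had an adjusted p of 4.43e-09 by camera, an adjusted p = 0.265 with an estimated correlation and an adjusted exact permutation p of 0.0192. The cartilage list fell in 12 of 15 genes and rose in 0 (13 over the list alone; camera adjusted p = 9.89e-06; adjusted p = 0.377 with an estimated correlation). Comp fell by 1.61 ± 0.27 and Matn3 by 3.71 ± 0.68 (log2, SE), while the cartilage proteoglycan Acan stood at −0.14 ± 0.18 and the chondrocyte regulator Sox9 at −0.26 ± 0.25, neither past the threshold. The fall of Matn3, a gene of 0.106 CPM in antagonist ears, was 4.45 without antagonist replicate 4.

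Cell division genes fell in 22 of 26 tested members and rose in 0 (25 when adjusted over the list alone). Top2a, a topoisomerase of dividing cells, fell from 125 ± 24.2 to 65.3 ± 10.2 CPM and the replication helicase subunit Mcm3 from 42.2 ± 3.24 to 29.5 ± 2.10 CPM (SD, n = 5). The list had an adjusted p of 1.87e-09 by camera and an adjusted p = 0.377 with an estimated correlation. Red blood cell genes fell in 5 of 7 members (7 over the list alone; camera adjusted p = 0.00276; adjusted p = 0.377 with an estimated correlation), but Hbb-bs lost its call without any one of 9 of the 10 libraries, with adjusted p from 0.0501 to 0.110. By edgeR, Alas2 lost its call without vehicle replicate 3 (adjusted p = 0.0672), vehicle replicate 11 (0.0521), antagonist replicate 6 (0.0589) or antagonist replicate 8 (0.0504). Hbb-bt lost its call without vehicle replicate 3 (0.0565).

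Genes of itch signalling moved in both directions. Of 37 tested members 13 fell and 4 rose (13 and 6 when adjusted over the list alone). Nppb, the natriuretic peptide that itch neurons use as a transmitter, fell from 1.47 ± 0.440 to 0.265 ± 0.110 CPM, a low level in skin. Htr7, a serotonin receptor, fell from 5.16 ± 0.780 to 1.71 ± 0.563 CPM, Il31ra, the interleukin 31 receptor, from 2.33 ± 0.529 to 0.884 ± 0.174 CPM and Hdc, which makes histamine, from 192 ± 46.2 to 94.9 ± 18.9 CPM (SD, n = 5). The 4 risers, named after their values were seen, were the opioid precursor Penk (0.72 ± 0.16, log2, SE), the endothelin receptor Ednra, the natriuretic peptide receptor Npr1 and the channel Trpv3. The list was near the threshold, with an adjusted p of 0.0454 by camera and an adjusted p = 0.377 with an estimated correlation. It missed the threshold without vehicle replicate 9 (adjusted p = 0.0521), vehicle replicate 10 (0.0807), antagonist replicate 4 (0.0589) or antagonist replicate 8 (0.0569). It also missed it with upper-quartile factors (0.0514), limma-voom (0.0598), 1 surrogate variable (0.0542), the muscle (0.0836), hair follicle (0.0740) and interferon (0.0527) covariates and TPM (0.166 and 0.177), and passed in 14 of 27 alternatives.

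Of 41 tested genes of epidermal differentiation and barrier, 14 rose, 2 fell and 25 did not pass (14 and 2 when adjusted over the list alone). The falls, named after their values were seen, were Lce3a and Lce3b, late cornified envelope genes of injured epidermis. Aloxe3, a lipoxygenase of the skin lipid barrier, rose from 51.5 ± 5.65 to 83.4 ± 11.1 CPM and the late cornified envelope gene Lce1d from 212 ± 12.8 to 298 ± 32.7 CPM (SD, n = 5). The list had an adjusted p of 0.00104 by camera, an adjusted p = 0.445 with an estimated correlation and an adjusted exact permutation p of 0.157 for its mean. Late cornified envelope genes are close copies of each other, and reads may have been shared among them. Hair follicle genes rose in 6 of 15 members and fell in 0 (6 over the list alone; camera adjusted p = 0.0216; adjusted p = 0.560 with an estimated correlation), with the homeobox gene Msx2 rising by 1.11 ± 0.18 and the hair keratin-associated gene Krtap3-2 by 1.04 ± 0.18 (log2, SE). The hair list missed the threshold without vehicle replicate 9 (adjusted p = 0.0859), vehicle replicate 12 (0.0665) or antagonist replicate 4 (0.109). It also missed it under DESeq2 (0.200), with no filter on low counts (0.656), under fry (0.0599) and with the interferon covariate (0.0527), and passed in 18 of 27 alternatives. One of the 27, the hair follicle covariate (0.376), is the list's own score and so cannot test it. The adjusted exact permutation p of the hair list's mean was 0.167.

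**Figure D2:**
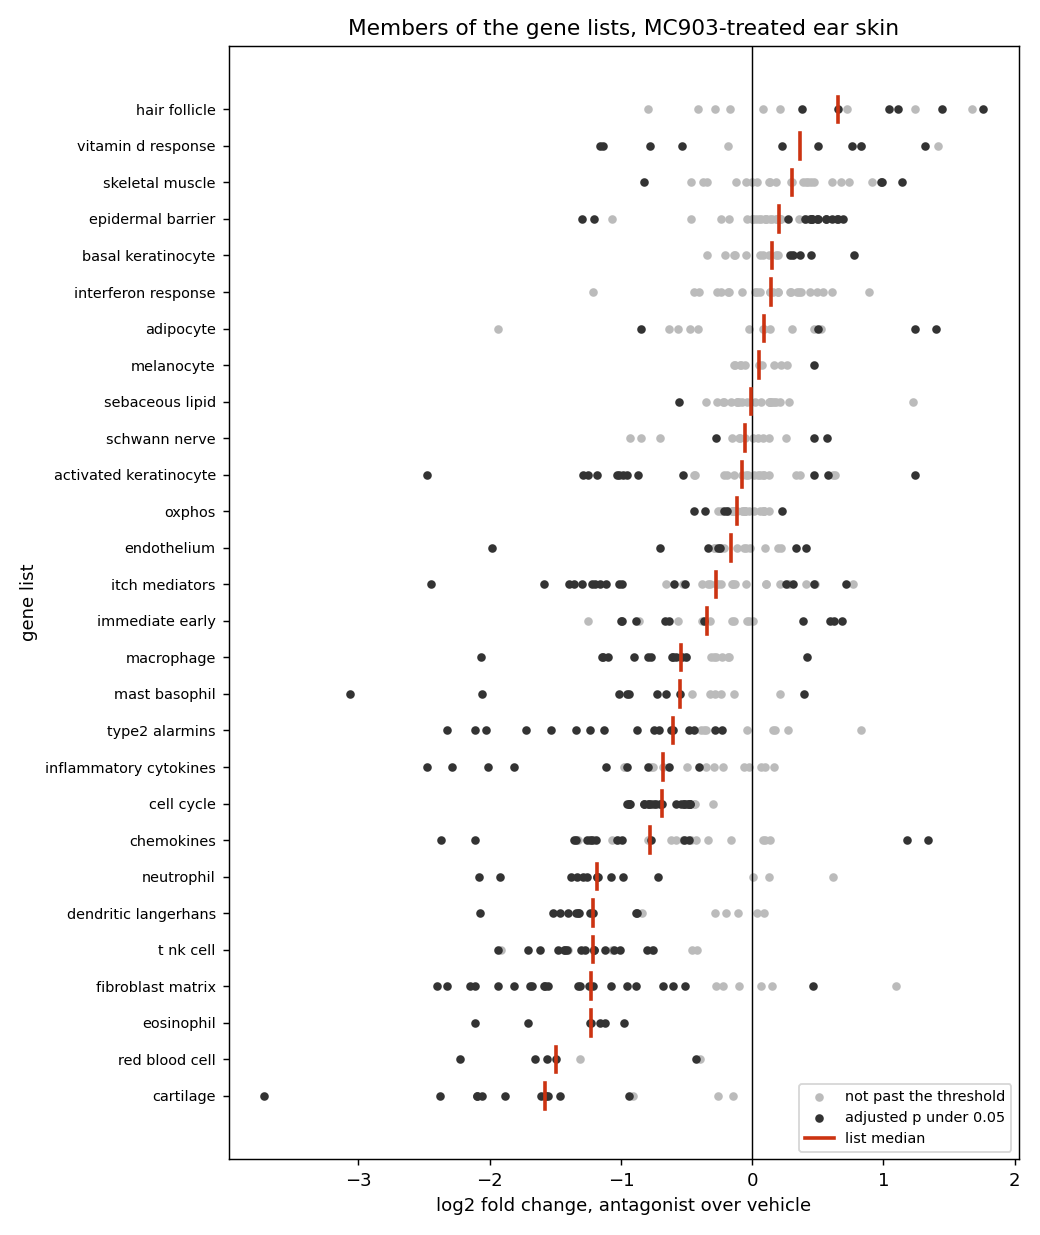
Log2 fold change of antagonist over vehicle (x axis) for each tested member of 28 gene lists (y axis, ordered by median); dark points passed the adjusted p, grey points did not, and red bars are list medians. Medians reach −1.58 for cartilage and 0.65 for hair follicle genes.

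Other lists did not pass camera with all libraries and the chosen settings. Activated keratinocyte genes, such as the antimicrobial S100a8 and S100a9, had 10 falls and 3 rises among 31 members (10 and 4 over the list alone; camera adjusted p = 0.297). Il24, Hbegf and Serpinb3b were those with the smallest p, and Krt6a, a keratin of stressed epidermis, stood at −0.076 ± 0.16. Vitamin D response genes split, with 5 rises and 4 falls among 12 (6 and 4 over the list alone; adjusted p = 0.664). Immediate early genes had 4 rises and 6 falls among 20 (the same over the list alone; 0.154), and oxidative phosphorylation genes 1 rise and 4 falls among 27 (the same; 0.0711). Endothelial genes had 2 rises and 5 falls among 18 (the same; 0.164), and one of the falls was Sele, the E-selectin that captures leukocytes, from 34.6 ± 3.81 to 8.73 ± 2.43 CPM (SD, n = 5). Basal keratinocyte genes had 5 rises and 0 falls among 16 (4 and 0; 0.117), skeletal muscle genes 3 rises and 1 fall among 25 (0 and 0; 0.154), adipocyte genes 3 rises and 1 fall among 16 (2 and 0; 0.813), sebaceous and lipid synthesis genes 0 rises and 1 fall among 22 (0 and 0; 0.813), melanocyte genes 1 rise and 0 falls among 11 (0 and 0; 0.718) and Schwann cell genes 2 rises and 1 fall among 15 (2 and 1; 0.813). None of 26 interferon response genes passed (0 over the list alone; 0.380), and the list's score varied widely among the antagonist libraries, at 4.69 ± 1.67 against 5.11 ± 0.62 in vehicle libraries (SD, n = 5). With an estimated correlation 0 of the 29 lists were called by camera, while fry called 15. The endothelial list, not called by camera, had an adjusted exact permutation p of 0.0192 for its mean. Some of these lists passed under alternatives. The oxidative phosphorylation list passed in 8 of 27, with adjusted p of 0.0217, 0.0308 and 0.0228 without antagonist replicate 7, antagonist replicate 8 or vehicle replicate 11, 0.0432 with total counts, 0.0272 on TPM with either pseudocount, and 0.0478 and 0.0436 with the muscle and cartilage covariates. The muscle list passed without vehicle replicate 9 (0.0160) or antagonist replicate 4 (0.0453) and with the hair follicle (0.000923) and interferon (0.0425) covariates. The immediate early list passed without vehicle replicate 3 (0.0238), the basal keratinocyte list without vehicle replicate 12 (0.0472) and with the hair follicle covariate (0.0164), and the interferon list without antagonist replicate 10 (0.0179) and with the muscle covariate (0.0145). The endothelial list passed under fry (0.0213). With the cartilage covariate the endothelial (0.0207), activated keratinocyte (0.00889), interferon (1.46e-06), melanocyte (0.00205), Schwann cell (0.0165) and sebaceous (0.0382) lists passed, the last 2 with a turned direction. Median, mean and test differed in sign for the interferon, adipocyte and sebaceous lists.

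**Figure D3:**
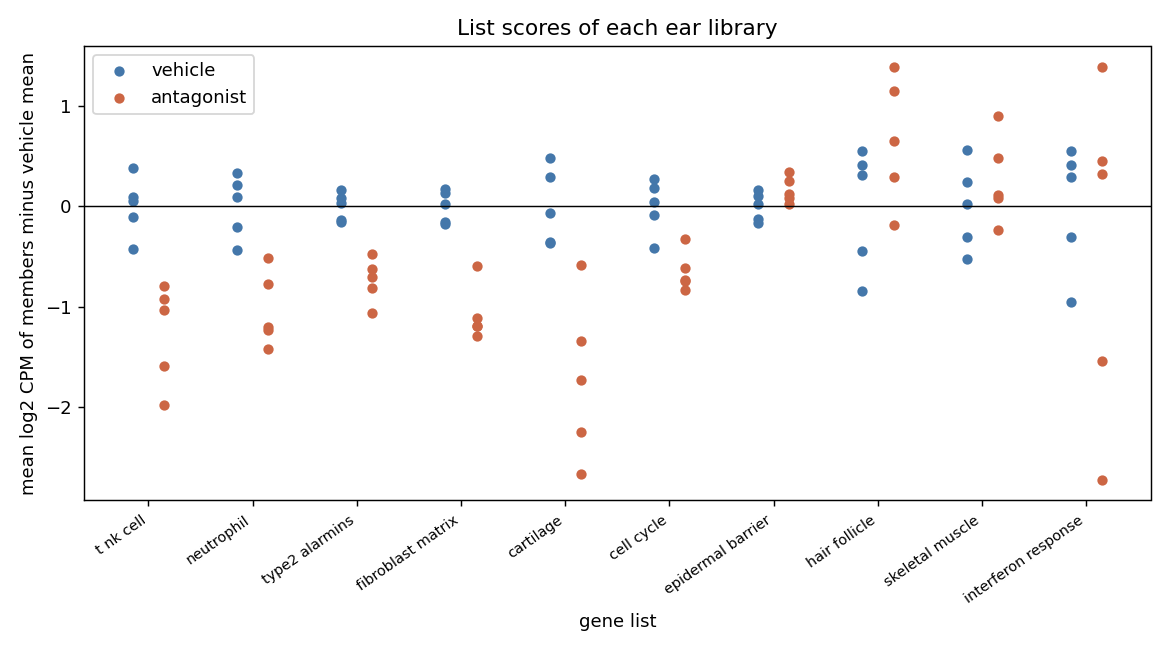
Mean log2 CPM of the members of 10 gene lists in each ear library, minus the vehicle mean of that list (y axis), by list (x axis) and group (colour); each point is 1 library of 5 per group. Antagonist libraries lie below all vehicle libraries for the T and NK cell, neutrophil, type 2, fibroblast and cartilage lists, and the interferon scores spread most among the antagonist libraries.

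Terms that the deposited table pairs with its genes gave an unselected view. By camera with a preset correlation, 31 of 874 gene ontology processes were called, 5 higher and 26 lower, and 59 of 315 KEGG pathways, 3 higher and 56 lower. The lower processes included adaptive immune response (44 of 80 genes fell and 4 rose), collagen fibril organization (23 of 33 fell and 2 rose) and neutrophil chemotaxis (22 of 39 fell and 1 rose). The higher ones were establishment of skin barrier (13 of 21 rose and 0 fell), bicellular tight junction assembly (13 of 25 rose and 2 fell), autophagy of mitochondrion (14 of 23 rose and 1 fell), K63-linked deubiquitination (12 of 26 rose and 0 fell) and translation (52 of 263 rose and 12 fell). The higher pathways were the ribosome, mitophagy and AMPK signalling. Their median log2 fold changes were 0.14, 0.10 and 0.13, and that of translation was 0.081. Among all 15174 tested genes 2530 rose and 2646 fell. With an estimated correlation 0 terms of either source were called. Other splits of the 10 libraries, some of them close to the real one, often called as many lists and terms, as given in the closing section.

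The authors' deposited table of their own comparison gave a similar count. It listed an adjusted p under 0.05 for 5561 of 19075 genes, 2765 higher and 2796 lower in antagonist ears. Of these, 5111 were also called here, all with the same direction, while 65 genes were called only here and 450 only in the authors' deposited table. Both comparisons rest on the same libraries, so the shared direction is no independent check.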

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

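The tests of epidermis and cartilage, and the covariates made from the cartilage and interferon lists, were chosen after the results were seen. Those tests were first run with intervals over genes, by which less cartilage had been excluded, and were replaced by intervals over libraries because genes are not independent. The count of genes called with the real groups, 5176, was reached by 1 of 100 splits of the 10 samples into 5 and 5, the real one included, drawn from 126 possible splits. The highest count of any other split was 36, so chance is argued against for the number of genes, at no finer than 1 in 100 splits. Mixed splits also place the difference between the groups within each side, which raises the spread and lowers their counts of genes. These splits cannot exclude chance for the number of lists and of terms called. Nor can they settle it, since splits close to the real one keep much of its contrast. The exact permutation test of each list's own mean is a separate test, which 16 of 29 lists passed after adjustment. They are not the same 16 that camera called: the 14 called lower passed it, and the 2 called higher, barrier (adjusted p = 0.157) and hair follicle (0.167), did not. With the real groups 16 gene lists were called, and 22 of 100 splits called as many, the highest of the others 21. For gene ontology processes the real count was 31, reached by 28 of 100 splits, the highest of the others 52, and for KEGG pathways it was 59, reached by 19 of 100 splits, the highest of the others 88. Each of these highest counts, of lists, processes and pathways, came from a split that exchanged 1 sample of each group. More mixed splits reached the real counts too, one of them with 19 lists, 47 processes and 75 pathways.

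The immune and matrix genes were lower in antagonist ears, with a difference of mean log2 CPM of −0.89 (95% interval over libraries −1.13 to −0.65) over 202 list members. A trend with GC content or gene length is argued against, since the members' median was −0.77 (−0.90 to −0.69, bootstrap over 201 members) after that trend was subtracted and −0.89 before. That bootstrap interval is over genes, which are not independent, and leaves out the spread between libraries. A larger share of epidermis diluting every other cell type as far as these members fell is argued against as well. The mean of 74 endothelial, Schwann cell, adipocyte and muscle genes differed by −0.030 (−0.26 to 0.20). That mean pools a higher muscle score (by 0.27) with differences of −0.20 for endothelial, −0.13 for Schwann cell and −0.21 for adipocyte genes. A smaller dilution is therefore not excluded. Less cartilage in the ear pieces stays open as a cause, whole or in part. With the cartilage score as a covariate the difference for the immune and matrix members was −0.87 (−1.34 to −0.39). That interval excludes 0 but reaches past the midpoint between 0 and the value without the covariate. The score may track the amount of cartilage imperfectly, so what remains after adjustment cannot exclude cartilage as the only cause. The score shared 69.7% of its variance with the groups, and in that model the median SE of the called genes grew by a factor of 1.80, while 5009 of 5176 kept their sign. The treatment itself stays among the open explanations, as does a difference between samples that the labels do not record.

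Single samples stood far from the rest of their group in 9 of 264 groups of 5 values tested, by Dixon's ratio of the gap to the range with a critical value of 0.71. Chance gives about 1 in 20 such groups, here 13.2, so the number itself is no more than chance would give. The ratio was 0.938 for Aloxe3 in the vehicle group, where replicate 3 was low at a log2 CPM of 5.38, and 0.712 for Lce1a2, where the same replicate was low. Prg2, an eosinophil granule protein, had a ratio of 0.725 with vehicle replicate 3 high. Vehicle replicate 10 was low for Il1rn, with a ratio of 0.791, and for Trim63, with a ratio of 0.817. The inflammatory cytokine list had a ratio of 0.738 with vehicle replicate 9 high. Antagonist replicate 4 was high for Arsi, with a ratio of 0.847, for Slc8a1, with 0.715, and for the mean of the fibroblast and matrix list, with 0.747, at 8.28 against 7.60 to 7.77 in the other antagonist libraries.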

How the results depend on the processing

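The covariates made from the cartilage and interferon lists were chosen after the data were seen. Library totals differed little, and how far depth limits scarce genes such as Uts2r was not tested. Across scaling, filters, DESeq2, limma-voom, robust estimation, the other covariates, 1 surrogate variable and deposited TPM, 4071 to 5738 genes were called, and 0 of the genes shared with the edgeR result had the opposite sign. Only genes called in both were compared, in the same libraries, so this agreement of sign was nearly certain beforehand. No paired analysis was possible because the groups share only replicate number 10, and a shared number alone does not show a pair.

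Leaving out 1 library gave 3850 (without antagonist replicate 6) to 5641 called genes (without antagonist replicate 4), 1880 to 2776 higher and 1966 to 2865 lower, 15 to 18 lists, 29 to 38 gene ontology processes and 51 to 74 KEGG pathways. Requiring a 2-fold change left 821 genes, 224 higher and 597 lower, because that criterion is stricter. It does not apply to the list tests. With the cartilage covariate 0 genes were called by edgeR, 0 higher and 0 lower, with 1841 at an unadjusted p under 0.05; the score shared 69.7% of its variance with the groups. With an estimated correlation camera called 0 lists, 0 gene ontology processes and 0 KEGG pathways, with 3, 25 and 29 at an unadjusted p under 0.05; fry called 15 lists.

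The log2 fold change of Uts2r turned negative under limma-voom (−0.47), with the hair follicle (−0.60) or interferon covariate (−0.19), with 1 surrogate variable (−0.12) and on TPM (−0.22 with a pseudocount of 1, −0.47 with 0.1), and ranged from −0.29 to 0.36 without 1 library, −0.027 without vehicle replicate 12 and −0.26 without antagonist replicate 7. With the cartilage covariate Alas2 (0.17), Hbb-bs (0.52), Hbb-bt (0.064) and Pdk4 (−0.44) turned. The direction of some lists turned, with these adjusted p by camera. The interferon list turned under DESeq2 (0.813), robust estimation (0.813) and the hair (0.0999) and interferon (0.691) covariates. The Schwann cell list turned under DESeq2 (0.992), robust estimation (0.985), the cartilage covariate (0.0165) and TPM (0.941 and 0.953). The sebaceous list turned under robust estimation (0.990) and the muscle (0.997) and cartilage (0.0382) covariates. The adipocyte list turned with the hair covariate (0.582), and the melanocyte list with the hair (0.420) and interferon (0.855) covariates. With the cartilage covariate the cartilage (0.576), immediate early (0.912), red blood cell (0.572) and vitamin D (0.576) lists turned. Without 1 library the adjusted p ranged from 0.0179 to 0.854 for the interferon list, from 0.470 to 0.990 for the Schwann cell list, from 0.434 to 0.923 for the sebaceous list and from 0.421 to 0.999 for the adipocyte list, and each turned in at least 1 of these. The cartilage and interferon lists were adjusted for their own scores by the covariates of those names, so these turns say nothing of their stability. Except where given, the cause was not tested.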

Other observations

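Genes of the immediate early list, which answer cell stimulation and stress, moved apart. Of 20 tested members 6 fell, among them the transcription factors Fos (−0.89 ± 0.25, log2 fold change ± SE), Atf3 (−0.99 ± 0.23) and Nr4a3 (−1.002 ± 0.25), and 4 rose, Hspa1a and Hspa1b, which encode heat shock protein 70, Egr3 and Btg2. Close copies of the Sprr2 family, small proline-rich proteins of stressed epidermis, moved in opposite directions, Sprr2b by 1.24 ± 0.31 and Sprr2f by −1.18 ± 0.31, and reads may have been shared among them, which was not tested. These genes, apart from Hspa1a, were named after their values were seen.

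In protein glycosylation 49 of 146 tested genes fell and 10 rose, and in the KEGG pathway of DNA replication 20 of 35 fell and 0 rose. The KEGG ribosome pathway had 27 rises and 5 falls among 134 genes, with a median log2 fold change of 0.14. Among all 15174 tested genes 2530 rose, and camera with an estimated correlation gave the ribosome an unadjusted p of 0.486.

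The tests of skeletal muscle, and of epidermis for vitamin D targets, were chosen after the results were seen, and replaced comparisons with the genes first seen alone, made with intervals over genes and then over libraries, which had argued against both explanations. Genes known to answer FoxO transcription factors or glucocorticoid, such as Trim63, Fbxo32, Klf15, Txnip and Zbtb16, had risen, so lists of further targets whose values had not been seen were tested as hypotheses. Of 21 FoxO targets 16 rose and 1 fell (17 and 1 when adjusted over the list alone), with a median log2 fold change of 0.39 at percentile 100.0 of 10000 random lists matched on expression (camera adjusted p = 1.22e-05; adjusted p = 0.247 with an estimated correlation). Of 22 glucocorticoid targets 8 rose and 1 fell (11 and 1 over the list alone), with a median of 0.39 (−0.067 to 0.54, bootstrap over members) at percentile 100.0 (adjusted p = 0.247 with an estimated correlation), and of 21 fat oxidation genes 5 rose and 0 fell (the same over the list alone), with a median of 0.14 at percentile 95.9 (adjusted p = 0.388 with an estimated correlation). More skeletal muscle in the ear pieces stays open: the muscle list differed by 0.27 (95% interval over libraries −0.36 to 0.90), and with its score as a covariate the mean log2 CPM of 56 members, 13 of them chosen because they had risen, differed by 0.54 (0.24 to 0.85) against 0.63 without it, an interval that excludes 0 but reaches past the midpoint between 0 and 0.63. A FoxO programme, a glucocorticoid response, a fasting switch or more muscle may each account for the rises and were not separated, and random lists ignore the correlation between genes.

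The fixed vitamin D list split, with 5 rises and 4 falls among 12 genes (6 and 4 over the list alone; camera adjusted p = 0.664): Slc8a1 (by 1.16 ± 0.14, log2, SE), Cd14, Thbd and Spp1 fell. Among the targets that rose Cyp24a1, which degrades vitamin D, rose from 1564 ± 752 to 3883 ± 964 CPM (SD, n = 5), and Vdr, Trpv6 and Cst6 were chosen with it because they rose. Of 12 further targets tested as a hypothesis 5 rose and 0 fell (the same over the list alone), with a median of 0.26 at percentile 99.4 of the random lists (adjusted p = 0.247 with an estimated correlation). A larger share of epidermis stays open: 57 basal and barrier genes differed by 0.16 (−0.0082 to 0.32), and with their score as a covariate the mean log2 CPM of these 4 and the 12 further targets, without the genes that fell, differed by 0.42 (0.048 to 0.79) against 0.42 without it, an interval that reaches past the midpoint between 0 and 0.42. More MC903 signal reaching the receptor may also account for the rises, and how much MC903 each ear received was not measured.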
